A study of Mus musculus with 8 samples.

How the data were processed

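RNA of 8 samples of sorted mouse OT-I CD8+ T cells was sequenced, 4 from co-cultures with DMSO and 4 from co-cultures with 2 µM RGX-104. Libraries were made from total RNA with a Lexogen 3′ FWD kit, which reads the ends of transcripts, per the labels' protocols, so a value reflects reads near a transcript's end. The table the authors deposited gives whole-number read counts per gene, not normalised. STAR 2.7.8a, R 4.1.0, DESeq2 1.4 and the genome build GRCm38 are named in the submitters' processing notes. The counting tool, its strand setting, the handling of reads that map to several places, the annotation release and any use of molecular identifiers are not given in the sources used here. Without molecular identifiers, reads made by PCR are not independent molecules, so counting precision covers counting error only.

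The table holds 41730 genes and other features in 8 columns, matched to samples by the number and group word in their titles. The symbols of 39351 of them (94.3%) were found in a RefSeq gene table of GRCm38.p6, from which coordinates were taken (1-based). A number is appended to the symbol in 2379 entries, of which 2339 repeat a symbol that also has its own entry. Of 1132 protein-coding genes with such a repeat, 763 (67.4%) are listed at 0 in all libraries, against 5815 of 20755 (28.0%) without one. Kif11, Atp5a1, Uqcrc1, Cdc45, Tnf, Ltb, Cd2, H2-Aa, H2-Ab1 and H2-Eb1 are listed at 0 in all libraries, which is therefore not read as absence of expression. Of 493 genes in the gene lists, 488 were in the table and 417 were tested. Symbols with a repeat (among the named genes Icos, Ctla4 and Il2) and near-identical globin genes are uncertain. Exons of 27 of 142 named genes overlap those of another gene by at least 100 bp in GENCODE M21, among them Srebf1 with Rai1 (109 bp), Pfkp with Pitrm1 (748 bp), Lpcat3 with Emg1 (334 bp), Psph with Cct6a (452 bp), Aars with Exosc6 (1326 bp, same strand), Ifng with Gm49751 (336 bp, same strand) and Tgfbr3 with Gm43422 (297 bp, same strand). Mitochondrial protein-coding genes were not analysed here.

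Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalisation, estimateDisp, and the quasi-likelihood test (glmQLFit without robust estimation, glmQLFTest, two-sided) with group as the only term, over all 8 libraries. Adjusted p-values are Benjamini-Hochberg values over the 12162 genes tested, and the threshold was 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM were computed here by dividing counts by the TMM-scaled library size. The biological coefficient of variation was 14.5%. Pairs of libraries within a group differed by 6.60 to 10.1 times the chi-square expected from counting noise, so no pair of libraries agreed within counting noise. Replicate numbers are not shared between groups, so no pairing was used. No column of the table belonged to another series (0 columns).

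Gene lists, the rule for named genes, the tests of the groups and lists in the report and the alternative settings were fixed before the data were examined, apart from the removal of repeated symbols and the tests named in the closing section as chosen later. The 18 process lists cover LXR targets, fatty acid synthesis, cholesterol synthesis, T cell activation, cytotoxic and effector cytokine genes, inhibitory receptors, naive and memory T cells, S phase, G2 and mitosis, glycolysis, oxidative phosphorylation, the type I interferon response, the IL-2 and STAT5 response, the amino acid stress response, the unfolded protein response, immediate early and heat shock genes, chemokine receptors and homing, and apoptosis regulators. The 8 marker lists cover CD8 T cells, dendritic cells, macrophages and monocytes, neutrophils, B cells, CD4 and regulatory T cells, NK cells, and erythroid cells and platelets. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over all 26 lists. Of the 11 lists called, 6 held with a correlation estimated per list. These were LXR targets, fatty acid synthesis, the IL-2 and STAT5 response, the amino acid stress response, CD8 T cell markers and the NK list. The NK list was reduced to Eomes, so it had no correlation between genes to estimate and shows no more than that gene. Counts of called members are given over all genes tested and adjusted over the list alone.

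Named genes were chosen by rule. The first part took the 10 genes with the largest log2 fold change in each direction among called genes with a mean of at least 20 counts and no overlap between the groups' libraries in CPM, leaving out unnamed gene models and markers of other cell types. The second part took the 3 tested members of each list with the smallest p. The last part always took Abca1, Abcg1, Srebf1, Mylip, Ifng, Gzmb, Il2ra and Cd69. Together these were 86 genes. A further 56 were chosen after their values were seen: 33 called members of the lists or aminoacyl-tRNA synthetases, 11 genes that were not called and 12 called genes outside the lists. Values of some genes are not reported here.

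On counts simulated from the real means, dispersions and library sizes with 200 genes changed (11920 genes passed the filter), the test recovered 24 of 65 genes changed by 0.5 on the log2 scale, 46 of 62 changed by 1 and 59 of 62 changed by 2, and 5 of its 134 calls (3.73%) were false. With 1 list moved by 0.4, camera called that list and 0 others of 26. Genes were simulated independently of each other, so this does not show how camera behaves on correlated genes. Alternative settings were RLE, upper-quartile and library-size scaling, DESeq2 1.42.0, limma-voom, robust dispersion, no filter on low counts, at least 20 counts in 4 libraries, the level of dendritic cell and macrophage markers as a covariate, each library left out in turn, and for the lists an estimated correlation, the rotation test fry and removal of members shared between lists. Removal of genes whose symbol is repeated was added after the data were seen. Library measures were compared with exact two-sided permutation tests over 70 arrangements.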

Results

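The series measured RNA in OT-I CD8+ T cells, mouse T cells whose transgenic receptor recognises the ovalbumin peptide SIINFEKL. The cells had been cultured with dendritic cells grown from bone marrow and loaded with that peptide, and were then purified by flow cytometry. Cultures received either the solvent DMSO (control, 4 libraries, replicates 1 to 4) or 2 µM RGX-104, a synthetic agonist of the liver X receptors (LXR), nuclear receptors activated by oxidised cholesterol (4 libraries, replicates 5 to 8). The comparison asks which transcripts of the T cells differ when the co-culture contains the agonist. Total counts per library ranged from 13144704 to 15966972. The labels do not say whether the libraries came from separate cultures or animals, so every p-value measures only the spread between these samples, which may be technical.

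RGX-104 libraries held more RNA of LXR target genes and of fatty acid synthesis genes, and far less RNA of genes of the amino acid stress response. Abca1, which exports cholesterol from cells, rose from 8.13 ± 0.569 to 85.2 ± 5.42 CPM (reads scaled to a common library size; mean ± SD, n = 4 per group). Trib3, a pseudokinase induced by amino acid shortage, fell from 53.5 ± 5.28 to 7.47 ± 1.08 CPM. Transcripts of the cytotoxic protease granzyme B (Gzmb), of interferon gamma (Ifng) and of both CD8 chains were also higher. Of 12162 genes tested, 108 were higher and 216 lower in RGX-104 at an adjusted p under 0.05, and 11 of the higher and 45 of the lower genes differed by 2-fold or more.

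**Figure D1:**
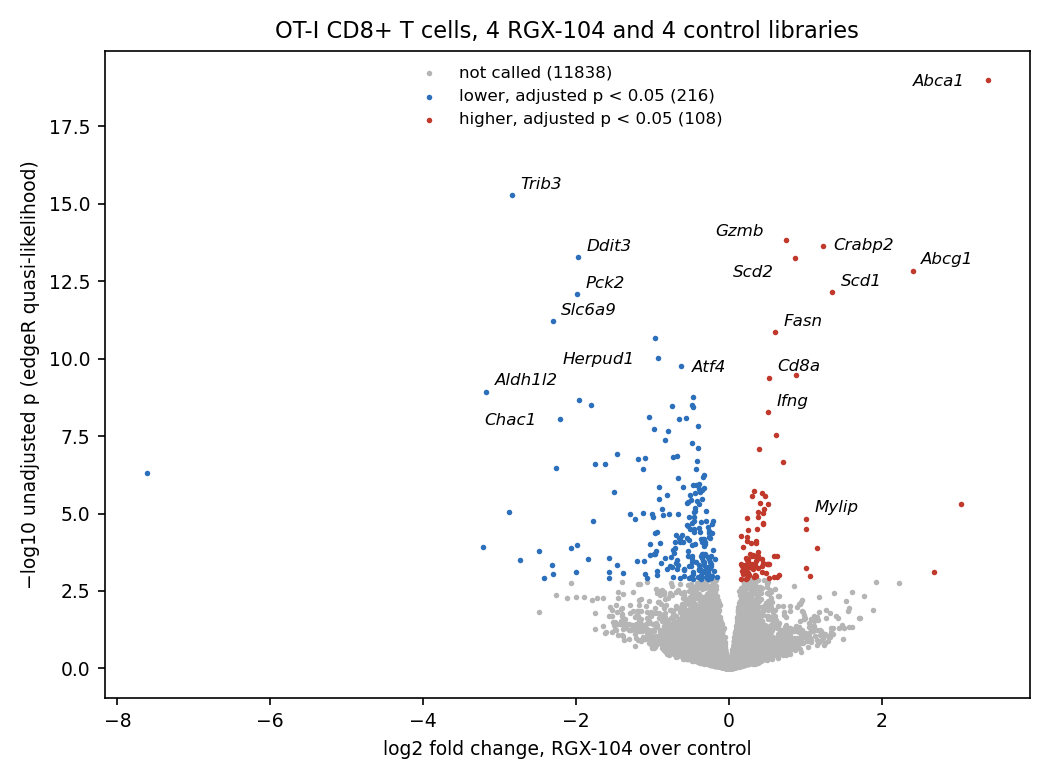
Each point is 1 of the 12162 tested genes, with its log2 fold change (RGX-104 over control, 4 libraries each) on the x axis and the negative log10 of its unadjusted edgeR p on the y axis; red points (108) were higher and blue points (216) lower at an adjusted p under 0.05, and grey points were not called. Abca1 lies at the top right and Trib3 is the highest point on the left, while the leftmost point is Extl1, which had 0 counts in all RGX-104 libraries, so that its fitted fold is no bound.

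Of 16 tested LXR target genes, 8 rose and none fell (8 and 0 when adjusted over the list alone; median log2 fold change 0.41; camera adjusted p = 1.98e-52, and adjusted p = 3.96e-05 with an estimated correlation). Abca1 (chromosome 4, 53030789 to 53159988) rose by 3.39 ± 0.11 on the log2 scale (± SE; adjusted p = 1.24e-15). Abcg1, a second cholesterol exporter (chromosome 17, 31057694 to 31117984), rose by 2.41 ± 0.15 on the log2 scale to 53.3 ± 8.28 CPM. Mylip, a ubiquitin ligase that degrades the LDL receptor (chromosome 13, 45389742 to 45411940), rose by 1.01 ± 0.18. Srebf1, the transcription factor that drives fatty acid synthesis (chromosome 11, 60199084 to 60224186), rose by 0.44 ± 0.08 from 58.0 ± 3.21 to 78.9 ± 6.26 CPM. Arl4c (0.87) and the phospholipid-remodelling enzyme Lpcat3 (0.47) completed the set together with the desaturases Scd1 and Scd2. Apoe, a lipoprotein component and an LXR target in macrophages, was at 10.3 and 11.2 CPM in control and RGX-104 (log2 fold change 0.12, adjusted p = 0.840).

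Of 17 tested fatty acid synthesis genes, 5 rose and none fell (6 higher and 0 lower when adjusted over the list alone; median log2 fold change 0.18; camera adjusted p = 4.74e-17, and adjusted p = 0.000748 with an estimated correlation). Scd1 (chromosome 19, 44394450 to 44407709) rose by 1.36 ± 0.09 from 37.9 ± 3.85 to 97.1 ± 8.41 CPM, and Scd2 on the same chromosome rose by 0.87 ± 0.05 to 569 ± 32.8 CPM. Fasn, the fatty acid synthase, rose by 0.61 ± 0.05, and Acaca, the acetyl-CoA carboxylase, by 0.39 ± 0.07. Scd1, Scd2, Srebf1 and Acsl3 stood in both lists. Cholesterol synthesis genes did not shift as a list: of 24 tested, 0 rose and 1 fell, Msmo1 (log2 fold change -0.46 ± 0.08, adjusted p = 0.00161). Adjusted over the list alone the counts were 0 higher and 3 lower, and the camera adjusted p was 0.165.

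**Figure D2:**
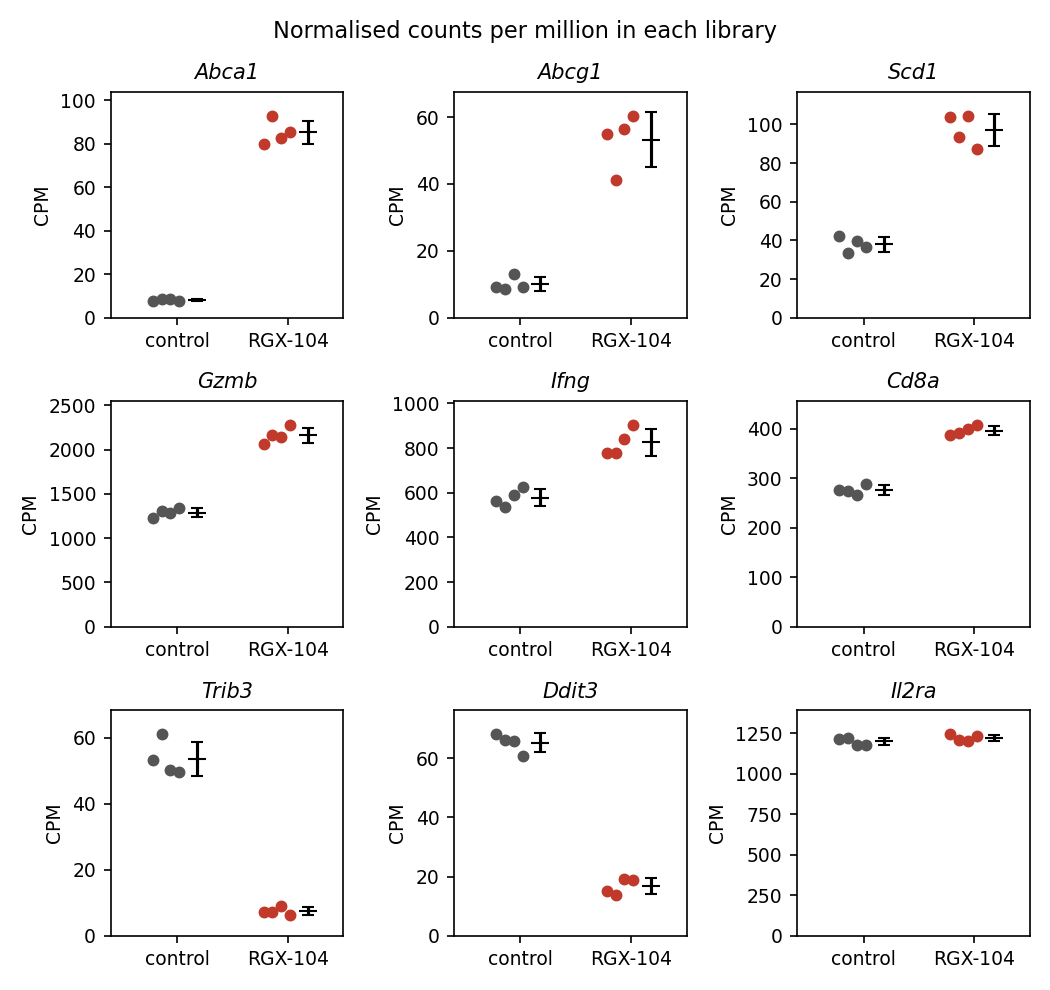
Normalised counts (CPM) of 9 genes in each library, with control libraries in grey and RGX-104 libraries in red; the bar beside each group is the mean with its SD (n = 4). Abca1, Abcg1, Scd1, Gzmb, Ifng and Cd8a lie higher in every RGX-104 library, Trib3 and Ddit3 lie lower in every one, and Il2ra lies between 1180 and 1245 CPM in all 8.

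The amino acid stress response genes, most of them targets of the transcription factor ATF4, fell together. Of 21 tested, 17 fell and none rose, and all 21 were lower when adjusted over the list alone (median log2 fold change -0.91; camera adjusted p = 7.92e-89, and adjusted p = 3.96e-05 with an estimated correlation). Trib3 (chromosome 2, 152337425 to 152344060) had a log2 fold change of -2.84 ± 0.13 (adjusted p = 3.18e-12). Ddit3, which encodes the stress transcription factor CHOP (chromosome 10, 127290793 to 127296291), went from 65.2 ± 3.22 to 16.7 ± 2.72 CPM, a log2 change of -1.97 ± 0.12. Atf4 itself went from 717 ± 56.6 to 466 ± 25.1 CPM (log2 fold change -0.62 ± 0.06, adjusted p = 1.50e-07). The glycine transporter Slc6a9 had a log2 fold change of -2.30, the glutathione-degrading enzyme Chac1 -2.21, the cystine transporter Slc7a11 -2.07 and asparagine synthetase (Asns) -0.91. Outside the list, the mitochondrial folate enzyme Aldh1l2 (-3.17) and the mitochondrial phosphoenolpyruvate carboxykinase Pck2 (-1.99, from 50.9 ± 5.45 to 12.8 ± 2.28 CPM) were among the 10 with the largest fall of the called genes with a mean of at least 20 counts and no overlap between the groups. Exons of Aldh1l2 overlap those of D10Wsu102e on the opposite strand over 1056 bp, and those of Slc6a9 overlap Ccdc24, so reads of these pairs could not be told apart with certainty.

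The unfolded protein response list was not called, with 2 of 18 tested genes higher and 2 lower (3 and 2 when adjusted over the list alone; camera adjusted p = 0.770). Its median log2 fold change was 0.05 and its mean -0.01, so these differed in sign. Herpud1, a component of endoplasmic reticulum degradation, fell by 0.93 ± 0.08 on the log2 scale and Sel1l fell by 0.28, while the chaperone Calr rose by 0.19 and Sdf2l1 by 0.34. Hspa5, the main chaperone of that compartment, was at 2139 ± 19.3 and 2032 ± 60.7 CPM (adjusted p = 0.373). Of 20 tested apoptosis regulators, 3 fell and 1 rose; those that fell were Bbc3 (log2 fold change -1.23), Bcl2 (-0.34) and Cflar (-0.30). Adjusted over the list alone, 1 was higher and 4 were lower, and the camera adjusted p was 0.165.

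Of 20 tested cytotoxic and effector cytokine genes, 4 rose and 1 fell (8 and 3 when adjusted over the list alone). The list's median log2 fold change was 0.33 and its camera adjusted p was 1.07e-06, but adjusted p = 0.05005 with an estimated correlation, just above the threshold. Gzmb (chromosome 14, 56258836 to 56262334) rose from 1287 ± 48.8 to 2162 ± 87.1 CPM, a log2 change of 0.75 ± 0.04 (adjusted p = 6.22e-11). Ifng (chromosome 10, 118441046 to 118445894) rose by 0.51 ± 0.06 from 578 ± 39.1 to 826 ± 59.2 CPM. The chemokine Ccl1 rose by 1.15 and Tnfsf10, which encodes the death ligand TRAIL, by 0.53. Serpinb9, an inhibitor of granzyme B, fell by 0.21. The perforin gene Prf1 had a log2 fold change of 0.41 (adjusted p = 0.0898), and Il2, uncertain because its symbol is repeated in the table, was at 12.1 ± 2.10 and 10.8 ± 2.53 CPM.

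T cell activation genes moved in both directions: of 25 tested, 8 rose and 3 fell (9 and 4 when adjusted over the list alone). The median log2 fold change was 0.14 and the camera adjusted p was 0.00489, with adjusted p = 0.140 with an estimated correlation. The adhesion receptor Cd44 rose by 0.33 ± 0.05, and Irf4 (0.24), Irf8 (0.23), Nr4a3 (0.36), Tbx21 (0.28), Tnfrsf18 (0.34) and Crtam (0.30) rose as well. Icos rose by 1.06 from only 2.84 CPM, and its value is uncertain because the table lists the symbol again with a number appended. The early activation marker Cd69 went from 124 ± 6.06 to 92.6 ± 5.82 CPM (log2 fold change -0.42 ± 0.07, adjusted p = 0.000649; chromosome 6, 129267324 to 129275375). The amino acid transporter subunits Slc3a2 (-0.39) and Slc7a5 (-0.28) fell too. Il2ra, the alpha chain of the interleukin 2 receptor (chromosome 2, 11642792 to 11693194), was at 1200 ± 23.2 and 1222 ± 19.6 CPM (log2 fold change 0.03 ± 0.04, adjusted p = 0.835).

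Of 17 tested IL-2 and STAT5 response genes, 5 rose and 1 fell (8 and 2 when adjusted over the list alone; median log2 fold change 0.17; camera adjusted p = 2.56e-08, and adjusted p = 0.0160 with an estimated correlation). Gzmb belongs to this list as well, and Il2rb (0.31), Socs2 (0.59), Pim2 (0.24) and the cyclin Ccnd2 (0.15) rose with it, while Nfil3 had a log2 fold change of -0.62. Among 11 tested CD8 T cell markers 4 rose and none fell (5 and 0 when adjusted over the list alone; camera adjusted p = 2.46e-11, and adjusted p = 0.00735 with an estimated correlation). Cd8a rose from 276 ± 9.58 to 397 ± 8.83 CPM, a log2 change of 0.52 ± 0.05, Cd8b1 by 0.39, the adaptor Lat by 0.39 and Thy1 by 0.19. Tested markers of CD4 and regulatory T cells (median log2 fold change -0.55) and of dendritic cells (-0.31) had negative medians but no called gene. The rotation test fry gave adjusted p of 0.00323 and 0.0149, while camera gave 0.177 and 0.209. Cd4 and Foxp3 were not among the 3 tested CD4 and regulatory T cell markers. These were Ctsl (-0.55, 8.20 CPM in control), Zbtb7b (-0.84, 2.53 CPM) and Cd40lg (-0.13, 2.92 CPM), too few and too low to show a shift of cell types. The share of each cell type was not measured. In the naive and memory list, Eomes, a transcription factor of effector and memory CD8 cells, rose by 0.62 ± 0.07 and Bcl2 fell by 0.34, and the other 18 of 20 tested genes were not called (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.506). Of 11 tested inhibitory receptor genes, Btla rose by 0.44 and none fell (1 and 1 when adjusted over the list alone; camera adjusted p = 0.678). Pdcd1, which encodes PD-1, had a log2 fold change of 0.05 (adjusted p = 0.955).

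**Figure D3:**
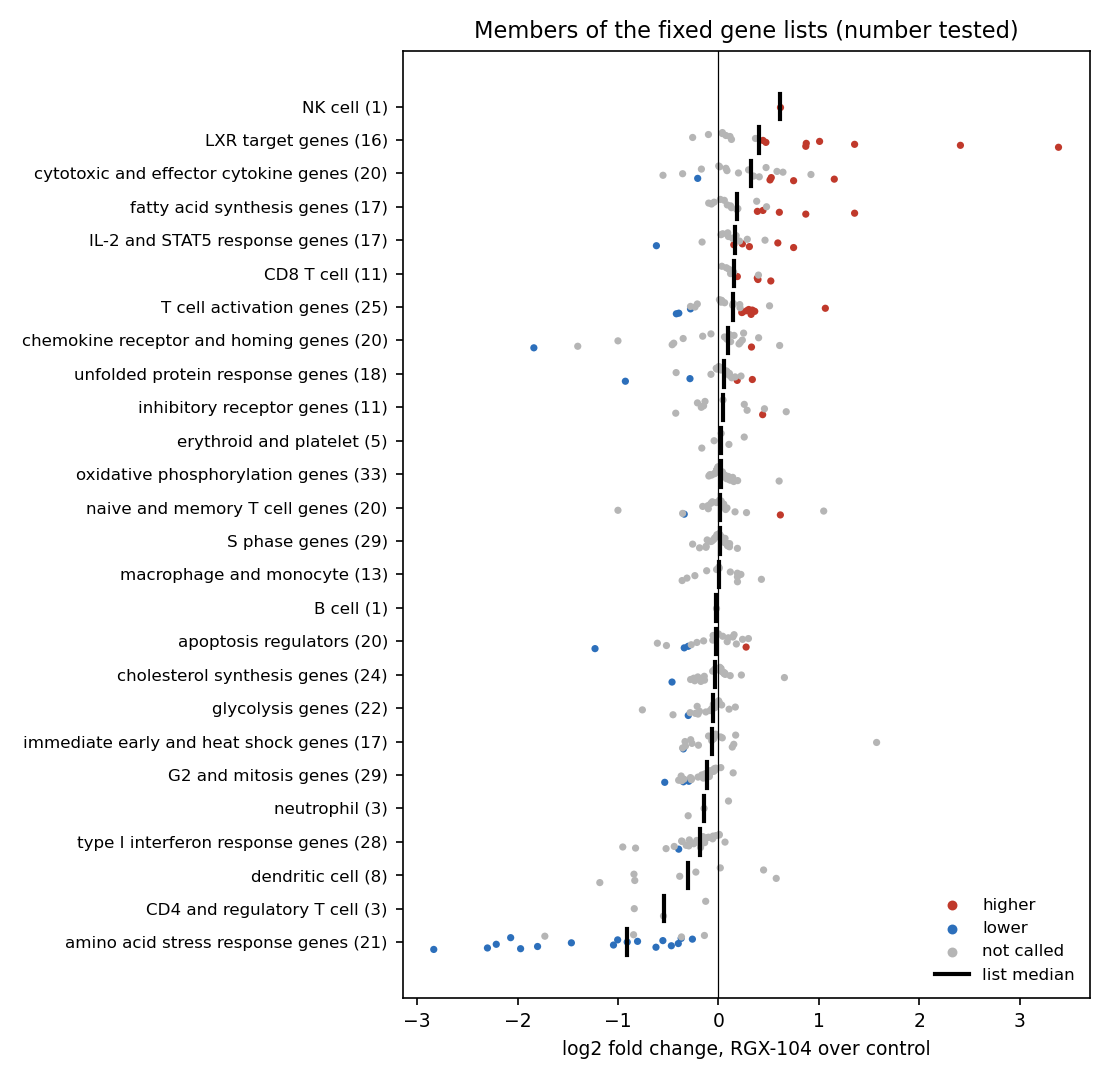
Log2 fold changes (RGX-104 over control) of the tested members of each gene list, with the number tested in parentheses; each point is a gene, red if called higher, blue if called lower and grey if not called, and the black bar is the list median. The amino acid stress response list has the lowest median (-0.91) and the LXR target list has a median of 0.41.

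The lists of G2 and mitosis, glycolysis and type I interferon response genes were lower by small amounts with the preset correlation and lost the call with an estimated one. Of 29 tested G2 and mitosis genes, Nusap1 (log2 fold change -0.53), Hmgb2 (-0.35) and Cenpe (-0.29) fell and none rose. Adjusted over the list alone, 0 were higher and 8 lower, and 27 of the 29 had a negative log2 fold change. The list's median was -0.12, with a camera adjusted p of 1.25e-05, and adjusted p = 0.291 with an estimated correlation. Its camera adjusted p ran from 3.29e-08 without RGX-104 replicate 5 to 0.00453 without RGX-104 replicate 8. In replicate 5, Cenpe (119 CPM) and Hmgb2 (310 CPM) lay within the control range, while Nusap1 (49.7 CPM) lay below it. Hmgb2 lay within its control range in replicate 6 as well (315 CPM). Mki67, which was not called, was at 243, 193, 155 and 136 CPM in replicates 5 to 8, against 223 to 246 in control. No gene of 29 tested S phase genes was called by edgeR, DESeq2 or limma-voom, and 4 had an unadjusted p under 0.05 (0 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.749). Of 22 tested glycolysis genes only the phosphofructokinase Pfkp fell by the test over all genes (log2 fold change -0.30), and 6 were lower when adjusted over the list alone (camera adjusted p = 0.00722, 0.0521 without RGX-104 replicate 5, and adjusted p = 0.291 with an estimated correlation). Of 28 tested type I interferon response genes only Trim30a (-0.40) fell, 2 were lower when adjusted over the list alone, and 25 had a negative log2 fold change (median -0.18; camera adjusted p = 0.00489, and adjusted p = 0.156 with an estimated correlation). Of 33 tested oxidative phosphorylation genes none was called by edgeR, over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05, and DESeq2 called 1, Cox5a. The camera adjusted p of this list was 0.120, with 0.0373 without RGX-104 replicate 5 and 0.0459 without the filter on low counts. Among 17 tested immediate early and heat shock genes Jun fell by 0.35 (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.209). Among 20 tested chemokine receptor and homing genes Selplg rose by 0.33 and Cxcr4 went from 4.19 ± 1.64 to 1.17 ± 0.645 CPM (3 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.764), with a median log2 fold change of 0.10 and a mean of -0.15.

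Other genes with a large change included Crabp2, a carrier of retinoic acid (chromosome 3, 87948693 to 87953372), which rose by 1.23 ± 0.07 from 73.2 ± 3.65 to 172 ± 13.3 CPM. Ankrd6 rose by 3.04 from 0.307 CPM, and Tgfbr3 and the lysophosphatidic acid receptor Lpar2 each rose by 1.01. Hoxb9 (log2 fold change -2.87), Gadd45a (-2.48), Glrp1 (-2.26) and Rab39b (-1.98) fell from control levels of 3.10 to 11.5 CPM.

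Leaving out Eomes of the NK cell list, the markers of other cells with the most counts were Cst3, Hbb-bs, Ctss and Hba-a1. In control and RGX-104, Cst3 was at 68.0 and 68.9 CPM and Hbb-bs at 66.9 and 64.9. Ctss was at 31.96 and 36.47 and Hba-a1 at 24.0 and 21.4 CPM. Cd74 was at 6.52 and 5.58 and Lyz2 at 3.74 and 4.06 CPM. Dendritic cell and macrophage markers together made up 0.0152% ± 0.000715 of counts in control and 0.0154% ± 0.00117 in RGX-104 libraries (exact two-sided permutation test, p = 0.771, n = 4 per group), and most of this was Cst3 and Ctss. H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1, dendritic cell genes listed at 0 with a repeated symbol, are missing from these shares, which are therefore too low by an unknown amount. None of 8 tested dendritic cell markers was called by edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05. Their median log2 fold change was -0.31 (camera adjusted p = 0.209; the rotation test fry, which tests the list by itself, gave 0.0149 for a lower level), and Ccl22 was at 3.66 and 1.61 CPM and Fscn1 at 4.23 and 2.37 CPM in control and RGX-104. The 13 tested macrophage and monocyte markers (camera adjusted p = 0.764), 3 neutrophil markers (0.764), 1 B cell marker, Cd79b (0.945), 3 markers of CD4 and regulatory T cells (0.177) and 5 erythroid and platelet markers (0.932) gave no called gene with edgeR, DESeq2 or limma-voom, and 1 of these genes, Ctsl, had an unadjusted p under 0.05. Fry gave an adjusted p of 0.00323 for a lower level of the CD4 and regulatory T cell list. Of the NK cell list only Eomes, which CD8 T cells also express, could be tested.

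Total counts were 1.54e+07 ± 513073 in control and 1.42e+07 ± 752266 in RGX-104 libraries (exact two-sided permutation test, p = 0.0571, n = 4 per group; Benjamini-Hochberg adjusted 0.257 over 6 library measures). Genes detected (p = 0.0857), the share of mitochondrial rRNA and tRNA (p = 0.171), the share of ribosomal protein genes (p = 0.8286) and the share of the 10 most abundant genes (p = 0.171) gave no exact permutation p under the threshold, where the smallest p the design allows is 0.0286. That test compares group means only. In RGX-104 replicates 5 to 8 the mitochondrial share was 4.90, 4.58, 4.11 and 4.05%. The ribosomal protein share was 9.97, 10.18, 10.65 and 10.94% in the same order. In control replicates 1 to 4 the mitochondrial share went from 5.01 to 4.65%, while the ribosomal protein share followed no such order. An effect of sample order was not tested. The first principal component, with 19.7% of the variance, separated the groups. With the mean level of dendritic cell and macrophage markers as a covariate, which had a correlation of -0.62 with the group, 31 genes were higher and 99 lower. The 324 genes called without it kept their direction, and their median absolute log2 fold change was 0.46 without and 0.48 with the covariate, while the median standard error went from 0.0843 to 0.108. The count of higher genes was 66 without control replicate 1, 57 without control replicate 2, 58 without control replicate 3, 65 without RGX-104 replicate 6, 61 without RGX-104 replicate 7 and 60 without RGX-104 replicate 8, and Icos, Btla, Cenpe, Cflar, Lpar2, Sdf2l1, Sel1l, Thy1 and Tnfsf10 each lost their call in 6 or 7 of these 8 fits.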

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

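In 296 groups of 4 values (142 genes and 6 library measures in both groups), 13 held a library far from the other 3, where chance alone gives about 14.8, so no pattern of such libraries was weighed. In control libraries, Abcg1 was at 13.12 CPM in replicate 3 against 8.536 to 9.183 in the others, and Chac1 was at 31.35 CPM there against 21.7 to 23.19. Cx3cr1 was at 4.101 CPM in the same library against 2.778 to 2.841, and Apoe at 8.075 against 10.92 to 11.29. Control replicate 1 had Herpud1 at 97.22 CPM against 111.4 to 113.7 and Cth at 18.41 against 17.14 to 17.35. Mylip was at 7.267 CPM in control replicate 4 against 10.35 to 10.92. Among RGX-104 libraries, replicate 5 had Msmo1 at 69.37 CPM against 74.85 to 75.93 and Mcm7 at 1252 against 1089 to 1113. Aars was at 130.5 CPM in replicate 6 against 151.4 to 152.6. Replicate 7 had Isg15 at 12.25 CPM against 14.8 to 15.16 and Nfil3 at 22.5 against 28.48 to 28.73. Lat was at 212.6 CPM in replicate 8 against 177.4 to 181.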

How the results depend on the processing

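Removal of genes with a repeated symbol was the only alternative chosen after the data were seen. The count of lower genes (216) stayed within 1.5 times under every alternative except the marker covariate, which gave 99. Fits without 1 library gave from 144 lower genes (without control replicate 3), at the edge of that range, to 211 (without RGX-104 replicate 5). These fits shared 192 and 256 of the 324 main calls. The count of higher genes (108) was 167 with DESeq2 and 31 with that covariate; of the 130 genes called with the covariate, 125 were among the 324, whose median absolute log2 fold change was 0.46 before and 0.48 after while the median standard error rose from 0.0843 to 0.108, so calls ended through the larger error. Leaving out 1 library gave 57 (without control replicate 2) to 93 (without control replicate 4) higher genes, with 66 and 58 without control replicates 1 and 3 and 65, 61 and 60 without RGX-104 replicates 6, 7 and 8; these fits had fewer samples. With an estimated correlation the adjusted p of the list was 0.140 for T cell activation, 0.05005 for cytotoxic and effector cytokine genes, 0.291 for G2 and mitosis, 0.291 for glycolysis and 0.156 for the type I interferon response. The interferon list was at 0.0509 with the covariate, G2 and mitosis at 0.0950 with fry, and glycolysis ranged from 0.000752 (without RGX-104 replicate 7) to 0.0521 (without RGX-104 replicate 5); these causes were not tested. Lists not called that passed in another setting were oxidative phosphorylation (0.0459 with no filter, 0.0373 without RGX-104 replicate 5) and, with fry, apoptosis regulators (0.0219), dendritic cell (0.0149) and CD4 and regulatory T cell markers (0.00323). Of 96 named genes that were called, 58 kept direction and call in every setting that tested them; of 46 not called, 13 passed the threshold in at least 1 setting, and 0 changed direction while called. Of the named genes, 22 lost their call without at least 1 of the 8 libraries, most often Icos (7 fits). At this depth 36.9% of simulated changes of 0.5 on the log2 scale were recovered.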

Other observations

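The tests on other splits of the libraries, on thinned counts and on scaling were chosen before their results were seen, and those on markers of other cells, on the unfolded protein response and on the synthetases after, with the rules for the markers and the unfolded protein response revised once their values were known. The 12 genes named here, chosen after their values were seen, had the smallest p among called genes with a gene name that stood in no list and were not already named, and all 12 were lower in RGX-104. Eif4ebp1, an inhibitor of cap-dependent translation, went from 111 ± 8.13 to 56.4 ± 3.54 CPM (log2 fold change -0.97 ± 0.08, edgeR adjusted p = 2.21e-08, n = 4 per group). Cth, which makes cysteine from cystathionine, went from 17.5 ± 0.590 to 4.51 ± 1.34 CPM (-1.95), and the GTP-binding protein gene Gtpbp2 had a log2 fold change of -0.83. The transcription factor gene Klf6 (-0.48), the histone demethylase gene Kdm4a (-0.75), Lmo4 (-0.48), Arap2 (-0.65), Pde4dip (-0.97) and Arl14ep (-0.80) fell as well, and the tRNA synthetase genes Nars (-0.47), Cars (-0.56) and Lars (-0.41) complete the 12.

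Of 18 tested genes for cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNA, 8 fell and none rose: Aars, Cars, Eprs, Gars, Lars, Nars, Sars and Tars. Of 17 tested mitochondrial ones edgeR, DESeq2 and limma-voom called none, and 0 had an unadjusted p under 0.05. The medians of the log2 fold changes were -0.08 and 0.05. A permutation test over genes gave p = 0.0673 for that difference of medians, and Fisher's exact test on the called members p = 0.00289. Genes are not independent replicates, and the median standard error was 0.0589 in the cytosolic and 0.153 in the mitochondrial set. The comparison was chosen after values were seen. Aars and Sars also stand in the amino acid stress response list, and Nars, Cars and Lars were picked above by their small p. The result of Fisher's test is therefore no independent support. Whether the 8 are the targets of ATF4 was not tested.

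Of the 35 splits of the 8 libraries into 4 and 4, only the real split gave as many called genes (1 of 35; 324 genes, highest other 3), so a random assignment of these 8 libraries to groups is argued against at the smallest share that 35 splits can give. A difference between cultures other than the compound is not addressed by it. After every library was thinned to 13144704 counts, 324 genes were called, 305 of them among the original 324, which argues against the deeper control libraries as the cause.

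The 95% bootstrap intervals in this paragraph and the next resampled genes, not libraries, and genes are not independent replicates. The rise of LXR targets was weighed against RNA of dendritic cells or macrophages, which the sort should remove. The 21 tested markers of those cells had a median log2 fold change of 0.0045 (95% bootstrap interval -0.23 to 0.19), where added cells would raise no gene more than their own markers; the 8 called LXR targets rose by 0.44 or more (median 0.94, and 0.41 over all 16 tested), which argues against more such RNA in the RGX-104 libraries. The summed rise of the 8 targets (554 CPM) was 3.62 times the summed level of all those markers (154 CPM; 3.09 to 3.83 over the RGX-104 libraries), but how much LXR target RNA such cells hold was not measured and H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1, listed at 0 with a repeated symbol, are missing from that level, so the ratio may be too large and induction in a trace of them stays open. A response of the T cells themselves to the agonist may account for the rise as well, and the 2 cannot be told apart here. An effect on the T cells through the dendritic cells of the co-culture was not tested.

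The median log2 fold change of the amino acid stress response list was at most -0.90 under the other scalings. These left the median of all tested genes between -0.0040 and 0.0068, too small a shift to move the list, so they decide nothing. A scaling shifts all genes nearly alike, and the list lay at -0.91 where all tested genes had a median of 0.0028. The list thus fell relative to the other genes. Lost cells lower no gene more than their own markers, and the macrophage and monocyte markers had a median of 0.0082 (95% bootstrap interval -0.12 to 0.19) against -0.91 (-1.73 to -0.55), which argues against loss of those cells. The dendritic cell markers had a median of -0.31 (-0.84 to 0.45), an interval that ends above -0.91 but overlaps that of the list, so a loss of dendritic cell RNA stays open: Ccl22 (-1.18), Fscn1 (-0.83) and fry (0.0149) go with it, while Cst3 (0.02) and Itgax (0.58) do not, and Trib3 (-2.84), Slc6a9 (-2.30), Chac1 (-2.21) and Ddit3 (-1.97) fell further than any of these markers. Less stress of the endoplasmic reticulum stays open, since the unfolded protein response list had a median of 0.051 (95% bootstrap interval -0.018 to 0.121) but members that went both ways, with Herpud1 (-0.93) and Sel1l (-0.28) lower and Calr (0.19) and Sdf2l1 (0.34) higher. Lower ATF4 activity from a better supply or a lower use of amino acids, or an action of the compound apart from LXR, may account for the fall too and was not tested.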
